A study of Mus musculus with 62 samples.

How the data were processed

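Per the labels, chromatin of mouse cerebral cortex was immunoprecipitated for H3K27ac, H3K4me3 or H3K36me3, or kept as input, and sequenced as 62 libraries from a MeCP2 knockout, a MeCP2 overexpression and a Dnmt3a conditional knockout cohort, each with its own wild-type group. Per the submitters' processing notes Bowtie2, bedtools and edgeR were used with the mm9 genome, without versions or roles. The peak caller, the filters and the library totals are not given in the sources used here. Replicate numbers are those of the labels, which do not say whether 1 mouse gave more than 1 library.

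The files used are 2 tables of the authors' own comparisons over the same 63596 regions, joined on chromosome, start and stop. They hold per region the log2 fold change of mutant over wild type and the mean log2 CPM, computed by the authors and, judging from column names alone, with edgeR by the authors. The p-value and FDR per region are the authors' as well, and recomputing Benjamini-Hochberg values from the deposited p-values gave the deposited FDR within 0.0003 in the knockout. A second log2 fold change and p-value per region, from a second test by the authors whose tool is not given in the sources used here, were used as an alternative. Methylation is deposited as the fraction of CA or CG calls that are methylated in each region at 2 and 8 weeks of age, with source and coverage not given, and is printed here as a percent. The region class, the gene, the knockout call, the combined MeCP2 call and the Dnmt3a call are text labels deposited by the authors. The meaning of "ua" is not given in the sources used here. No values per library were in the tables used, so the design fixed beforehand, a count model per cohort, was replaced by summaries of these comparisons, and no library could be left out, relabelled or paired.

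The 5% FDR threshold of the fixed design was applied to the deposited FDR. The deposited knockout call equals an FDR below 0.1, with 0 mismatches. Means, differences and correlations over regions were given SDs and 95% intervals by resampling the 276 10-Mb genome bins that hold regions 1000 times. Overlaps were tested with Fisher's exact test and with Mantel-Haenszel odds ratios over strata, with Benjamini-Hochberg adjustment within each family. Overlaps of the combined call were taken over the 45252 enhancer and ua_acetylpeak regions with a combined label, leaving out 60 without one, and overlaps of the knockout FDR calls over all 63596 regions. The gene test was taken over the 28439 labelled regions inside genes, 539 of them higher in the knockout and lower in overexpression. Gene lists were tested with limma's cameraPR on signed z values of the deposited p-values with a preset correlation of 0.01, over 26 tests (13 lists in 2 cohorts). Stouffer's method on the same z values, with the overexpression sign reversed, gave a contrast of the 2 MeCP2 cohorts. An estimated correlation needs values per library, so 10000 circular shifts of the z values along the genome stand in its place.

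Regions to name were fixed before the data were examined: past an FDR of 0.05, the 12 largest gains and 12 largest losses among regions above the median read abundance, 1 per gene, plus Mecp2, Dnmt3a, Irak1, Bdnf and list members past the threshold. The further condition that every mutant library move the same way could not be applied. Regions shared with the Dnmt3a calls, genes with several combined calls, and list examples were chosen after their values were seen. Of 15499 gene symbols, 12682 match a current symbol of the GRCm38.p6 gene table and 1437 a synonym of 1 gene. Coordinates are those of the tables, in mm9.

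The genome-bin intervals, the stratified odds ratio and camera were tested on simulated data, and the other tests were not. Over 100 simulations on the 63596 regions, intervals covered a true correlation of -0.4 in 97% and a true enhancer difference of 0.1 in 93%. Over 20 simulations on 45312 regions, the stratified odds ratio averaged 0.992 with no link and 5.00 at a true ratio of 5. The simulated calls followed the same methylation values that formed the strata, so error in those values was not covered. Camera on knockout z values called 3% of 200 unshifted sets of 40 regions, 66% at a shift of 0.5 and 100% at a shift of 1. The z values were shuffled and the sets drawn at random, so lists with many neighbouring regions per gene were not covered. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Mean read abundance is the only measure of depth used, and how results differ in regions above its median is given with the alternatives.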

Results

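H3K27ac, a histone acetylation mark of active enhancers and promoters, was profiled by ChIP-seq in the cerebral cortex of 3 mouse cohorts. The first compared 5 libraries of male MeCP2 knockouts (KO) with 5 of wild-type males at 7 to 8 weeks. The second compared 3 libraries of males that overexpress MeCP2 (OE) with 3 of wild-type males at 7 to 10 weeks. The third compared 5 libraries of Dnmt3a conditional knockouts (cKO) with 5 of wild-type mice at 7 to 8 weeks, 4 labelled male and 1 female per genotype. MeCP2 is a nuclear protein that binds methylated DNA and is mutated in Rett syndrome, and Dnmt3a is the enzyme that places methyl groups on CA sites in neurons. The comparisons ask how H3K27ac at regulatory regions depends on MeCP2 level and on Dnmt3a. The 26 H3K27ac libraries are analysed here through the authors' comparison tables, and the 10 H3K4me3, 12 H3K36me3 and 14 input libraries are not analysed here.

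The tables cover 63596 regions of the mm9 genome: 32614 enhancers, 16529 promoters, 12698 acetylation peaks labelled ua_acetylpeak and 1755 promoters labelled ua_promoter. Of the enhancers, 21858 lay inside a gene and 10756 outside genes. Median length was 2377 bp for enhancers and 3057 bp for promoters. Median CA methylation at 8 weeks was 2.51% in enhancers and 1.35% in promoters, and median CG methylation was 65.5% and 23.1%. The depth of each library is unknown from these tables. The median over regions of the mean CPM, reads scaled to a common library total, was 7.69 in the knockout cohort and 8.91 in the overexpression cohort, and regions with fewer reads carry less precise fold changes.

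In the MeCP2 knockout, H3K27ac rose mainly at enhancers inside genes. At an FDR below 0.05 in the authors' deposited table, 158 regions were higher and 49 lower than in wild type. Enhancers inside genes gave 89 higher and 3 lower regions, against 19 higher and 25 lower outside genes (Fisher's exact test, two-sided, p = 2.0e-12, adjusted p = 3.3e-12 over 5 such splits). Promoters gave 21 higher and 13 lower regions, and the balance at all enhancers, 108 higher and 28 lower, did not differ from it after adjustment (Fisher's exact test, p = 0.043, adjusted p = 0.054). The authors' second test called 10 regions at an adjusted p below 0.05. All 207 regions had the same sign in that second test, where their median size was 0.45 log2 units in place of 0.63, and 52 of them were given no adjusted p.

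The region with the largest gain among those above the median read abundance was an enhancer in Mad1l1, which encodes a spindle checkpoint protein (chromosome 5, 140535225 to 140540222), with a log2 fold change of 0.93 and an FDR of 0.00020 in the authors' deposited table. An enhancer in Cdh4, the gene of R-cadherin (chromosome 2, 179481285 to 179486065), stood at 0.82 in the authors' deposited table, and one in Snx24, a sorting nexin gene (chromosome 18, 53449515 to 53451933), at 0.80. The smallest FDR of this group, 5.1e-10, belonged in the authors' deposited table to a long enhancer in Gm12824, now named Trabd2b (chromosome 4, 114138738 to 114152807), with a log2 fold change of 0.78, or 1.72-fold. Further intragenic enhancers with gains in the authors' deposited table were those of Fndc3b (0.73), Arhgap10, a Rho GTPase-activating protein gene (0.71), Inadl, now Patj, a cell polarity scaffold gene (0.71), and Nhsl2 on the X chromosome (0.70). The 1 gene promoter among the 12 largest gains was that of Agxt2l1, now Etnppl (chromosome 3, 130320073 to 130324660), at 0.69 with an FDR of 0.0018 in the authors' deposited table. The other 3 gains of this group lay outside genes, on chromosomes 1, 5 and 15, with log2 fold changes of 0.86, 0.73 and 0.71 in the authors' deposited table.

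Losses of the same rank lay mostly outside genes or at promoters. The largest was a ua_promoter region of Tchh, the trichohyalin gene (chromosome 3, 93247538 to 93252108), with a log2 fold change of -0.83 and an FDR of 0.00040 in the authors' deposited table. Promoters followed at Klhl1 (-0.68), Fgf11, a fibroblast growth factor homologous factor gene (-0.62), and Hkdc1, a hexokinase-domain gene (-0.60), all in the authors' deposited table. The promoter annotated to AL672002.1, next to Mecp2 (chromosome X, 71267742 to 71270211), stood at -0.68 with an FDR of 0.045 in the authors' deposited table. Outside genes, losses on chromosomes 8, 3, 13, 14, 19, 3 and 7 ranged from -0.75 to -0.60 in the authors' deposited table. Mecp2 itself has a single region here, its promoter (chromosome X, 71328999 to 71331941), with a knockout log2 fold change of -0.12 and an FDR of 0.83 in the authors' deposited table. The 2 Bdnf promoter regions stood at -0.09 and -0.25, with FDRs of 0.90 and 0.45 in the authors' deposited table. No region is annotated to Irak1.

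Averaged over regions, enhancers moved by 0.044 ± 0.0025 log2 units in the knockout (SD over 1000 resamplings of 10-Mb genome bins) and promoters by -0.040 ± 0.0017. The difference was 0.084 (95% interval 0.079 to 0.089), and its sign was the same on 20 of 20 chromosomes. Enhancers inside genes averaged 0.075, and those outside genes -0.019, a difference of 0.094 (0.085 to 0.103), again with 1 sign on 20 of 20 chromosomes. These intervals describe variation along the genome and not between mice, because values per library are not analysed here. In the authors' second test the intragenic difference was 0.060.

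**Figure D1:**
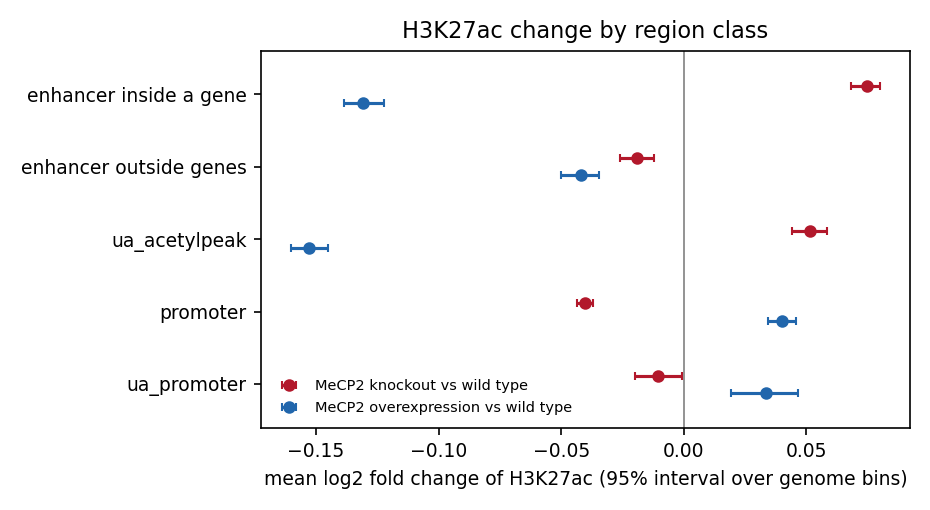
Mean log2 fold change of H3K27ac (x axis) for 5 region classes (y axis) in MeCP2 knockout (red) and overexpression (blue), with bars for 95% intervals over resampled genome bins. Enhancers inside genes stood at 0.075 in the knockout and -0.131 in overexpression, and promoters at -0.040 and 0.040.

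MeCP2 overexpression was accompanied by few changes that passed adjustment, led by the Mecp2 promoter. At an FDR below 0.05 in the authors' deposited table, whose column names are those of edgeR, 4 regions were higher and 0 lower, and at an unadjusted p below 0.05 the numbers were 1475 and 3296. The authors' second test, adjusted here, called 1 region. The Mecp2 promoter stood at a log2 fold change of 1.26, or 2.39-fold, with an FDR of 1.9e-07 in the authors' deposited table. The overexpression libraries are labelled Tg and input reads are not analysed here, so H3K27ac per copy of the gene is unknown. The other 3 were an enhancer outside genes on chromosome 15 (100990361 to 100994681, log2 fold change 0.90), an enhancer in Prrg2 on chromosome 7 (52313613 to 52315626, 0.79) and an enhancer outside genes on chromosome 9 (113064348 to 113073934, 0.57) in the authors' deposited table. These 3 had negative knockout fold changes in the authors' deposited table, -0.22, -0.36 and -0.18, none of which passed the FDR. At an FDR below 0.1 the only lower region was an enhancer in Nell1, at -1.02 in the authors' deposited table.

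The 2 other regions within 100 kb of the Mecp2 promoter stood at 0.37 and 0.51 in overexpression, with FDRs of 0.68 and 0.58, in the authors' deposited table. The median of the 474 other X-linked promoters was 0.15, and that of autosomal promoters 0.059. The averages of all enhancers, of enhancers inside genes and of promoters had the opposite sign to those of the knockout, while enhancers outside genes were below 0 in both cohorts. Enhancers averaged -0.102 ± 0.0035 and promoters 0.040 ± 0.0030 (SD over genome bins), a difference of -0.142 (95% interval -0.149 to -0.135). Enhancers inside genes averaged -0.131 and those outside -0.042, a difference of -0.089 (-0.098 to -0.079). Both signs held on 20 of 20 chromosomes, and in the authors' second test the differences were -0.087 and -0.054. Overexpression fold changes rose with the mean read abundance measured in the knockout cohort (Spearman's rho 0.280 over all regions, 0.152 at enhancers). By that measure promoters had more reads than enhancers, with medians of 4.24 and 2.83 log2 CPM. Among regions above the median abundance the enhancer-promoter difference was -0.125. The median over all regions was -0.051 in overexpression and 0.0076 in the knockout, and the mean -0.071 and 0.022, so the 2 cohorts have different centres. Of all regions, 41.6% lay above 0 in overexpression and 51.6% in the knockout. Signs against 0 depend on these centres. Enhancers outside genes, at -0.042 in overexpression, lay above the mean of all regions there, and at -0.019 in the knockout below it.

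Regions that gained H3K27ac without MeCP2 tended to have less of it with extra MeCP2. Of the 158 regions higher in the knockout, 154 had a negative overexpression fold change, with a mean of -0.43 (95% interval -0.47 to -0.39). Of the 49 lower regions, 44 had a positive one, with a mean of 0.26 (0.20 to 0.32). Over all regions 65.0% had opposite signs. Across the 63596 regions, which are not independent replicates, the fold changes correlated at Pearson's r = -0.388 (95% interval -0.397 to -0.379 over genome bins) and Spearman's rho = -0.389. The correlation was -0.401 at enhancers and -0.368 at promoters. Each cohort has its own labelled wild-type group.

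The authors' combined call marks 638 regions as higher in the knockout and lower in overexpression, and 189 as the reverse. The label is given to enhancers and ua_acetylpeak regions only, and promoters carry none. A Stouffer contrast of the deposited p-values, which does not require opposite signs, gave 82 promoter or ua_promoter regions with higher values in the knockout than in overexpression and 114 with lower ones at an FDR below 0.05. Fisher's method on the deposited p-values, adjusted over all regions to an FDR below 0.1 and limited to opposite signs and to enhancers and ua_acetylpeak regions, returned the same 638 and 189 regions. Such a call can rest mainly on 1 cohort. At an FDR below 0.1 in the knockout alone, 229 of the 638 and 63 of the 189 passed. In overexpression alone, 6 regions of any class were higher and 1 lower at that FDR. Inside genes the call gave 444 enhancers of the first kind and 50 of the second, against 72 and 123 outside genes (Fisher's exact test, p = 3.1e-44, adjusted p = 1.6e-43 over 5 such splits). The p-values of these splits, in each cohort, count neighbouring regions as independent and are therefore too small. Median fold changes of the 638 regions were 0.49 in the knockout and -0.55 in overexpression, and those of the 189 regions were -0.43 and 0.45, in the authors' deposited table. Since the calls were made on these fold changes, those medians are not independent evidence of size.

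Of the 638 regions 539 lay inside 370 genes, and they gathered in some of these. Rora, which encodes the nuclear receptor ROR-alpha (chromosome 9, 68501592 to 69236053), held 11 among 52 tested regions. Fbxl17, an F-box protein gene, held 7 among 26, Odz3, a teneurin gene, 6 among 15, Cdh4 6 among 20, Gm12824 5 among 11, and Nell1 5 among 17. Tshz1, a zinc finger transcription factor gene of 74.9 kb, held 4 among 5 and Inadl 4 among 8. Auts2, a gene linked to autism, held 6 among 46. In Rora 50 of 52 regions had a positive knockout fold change and 50 of 52 a negative overexpression one. The gene was picked for its combined calls, and its 11 called regions have these signs by definition. Among all enhancers inside genes 63.6% lay above 0 in the knockout and 29.6% in overexpression. Median CA methylation of the Rora regions was 5.00%, within the range of the highest enhancer decile. The test that follows did not allow for methylation. Of 2090 genes with at least 4 tested regions, 13 held more calls of the first kind, higher in the knockout, than their number of regions gives (hypergeometric test, adjusted p = 6.4e-06 for Rora and 0.036 for Auts2 and Smad3). The test counts neighbouring regions as independent, which makes these p-values too small.

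**Figure D2:**
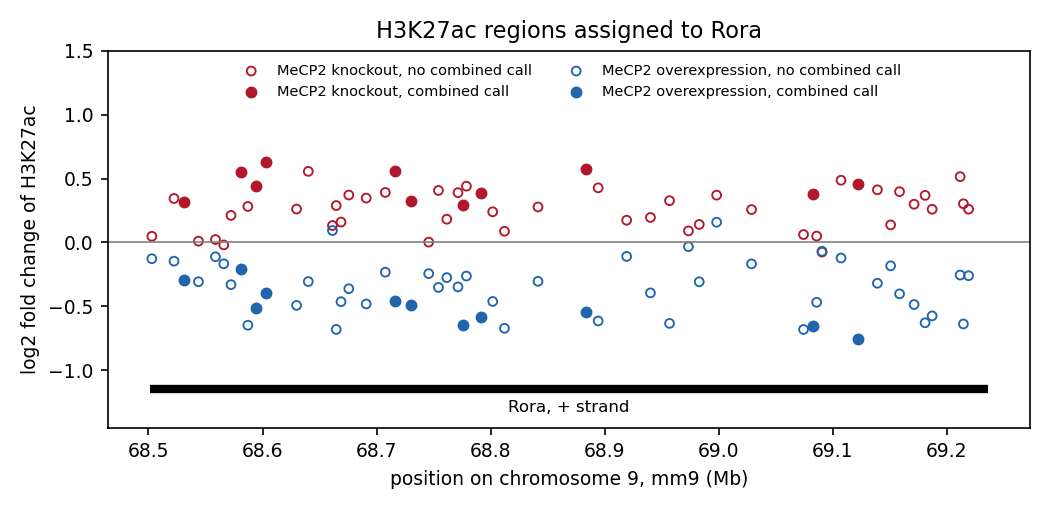
Log2 fold change of H3K27ac (y axis) at regions assigned to Rora against mm9 position in Mb on chromosome 9 (x axis), in MeCP2 knockout (red) and overexpression (blue). Filled points are the 11 regions with the combined call, open points the other regions, and the black bar is the gene. Knockout points lie mostly above 0 and overexpression points mostly below it.

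Opposite changes were larger where CA methylation was higher. In the decile of enhancers with the least CA methylation, at most 1.30%, the mean fold change was -0.025 in the knockout and -0.027 in overexpression. In the decile with the most, at least 4.40%, it was 0.164 and -0.221. The difference between these deciles was 0.190 ± 0.0062 in the knockout (95% interval 0.179 to 0.202) and -0.194 ± 0.0079 in overexpression (-0.210 to -0.178), with 1 sign on 20 of 20 chromosomes in each. In the authors' second test, whose fold changes have a smaller spread (SD 0.138 in place of 0.225 over knockout regions), the differences were 0.122 and -0.114. Deciles by CG methylation differed by 0.092 and -0.146. Across enhancers the knockout fold change correlated with CA methylation at 0.239 once CG methylation was accounted for, and with CG methylation at 0.069 once CA was (partial Pearson). The overexpression values were -0.218 and -0.109. At promoters CG methylation had the larger value in the knockout, 0.199 against 0.141 for CA, and over all regions in overexpression they were -0.201 and -0.206.

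**Figure D3:**
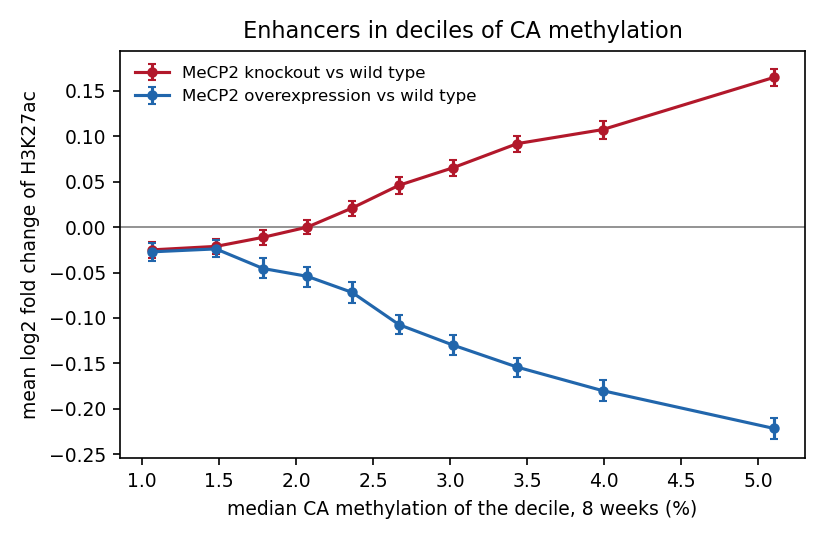
Mean log2 fold change of H3K27ac (y axis) in deciles of enhancers by CA methylation at 8 weeks, placed at the median percent of each decile (x axis), with 95% intervals over genome bins. Knockout means (red) run from -0.025 to 0.164 and overexpression means (blue) from -0.027 to -0.221.

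The share of combined calls also differed with CA methylation. Of the enhancers in the highest CA decile 5.33% were called higher in the knockout and lower in overexpression, against 0 of 3262 in the lowest. The reverse call stood at 0.674% in the lowest decile, was highest in the decile of rank 4 at 1.16%, and reached 0 of 3262 in the highest. The 638 regions had a median CA methylation of 3.90%, the 189 regions 1.98% and the other tested regions 2.59%. The gain in CA methylation per region from 2 to 8 weeks of age had a median of 1.02 percentage points in the first set, 0.518 in the second and 0.656 in the others. The coverage behind these methylation values is unknown, so no measurement error is given for them.

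In the Dnmt3a cKO the authors' calls marked 453 regions as higher and 424 as lower than in wild type. Enhancers gave 255 higher and 292 lower regions, promoters 77 and 107, and ua_acetylpeak regions 98 and 14, a split that differed from that of enhancers (Fisher's exact test, p = 1.1e-16, adjusted p = 2.7e-16). The split at enhancers did not differ detectably between those inside genes, 173 higher and 216 lower, and those outside, 82 and 76 (Fisher's exact test, p = 0.13, adjusted p = 0.13). A promoter region of Dnmt3a itself (chromosome 12, 3805042 to 3826892) was among the lower calls in the authors' deposited table. Regions called higher had a median CA methylation of 3.99% and those called lower 1.52%, against 2.32% elsewhere, while their median CG methylation was 62.2% and 67.6%. Fold changes and p-values of this comparison are not analysed here, and the threshold behind the calls is not given in the sources used here.

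Regions higher in the Dnmt3a cKO leaned the same way in the MeCP2 knockout. Their mean knockout fold change was 0.19 (95% interval 0.17 to 0.21), and 80.6% were above 0. Regions lower in the cKO averaged -0.10 (-0.12 to -0.08), a difference of 0.293 ± 0.015 (0.262 to 0.322). In overexpression the difference was -0.184 ± 0.018. Of the 638 regions higher in the knockout and lower in overexpression, 36 were also higher in the cKO, where independent lists would share 4.96, and 1 was lower (odds ratio for the higher calls 8.38, 95% interval 5.60 to 11.5 over genome bins, Fisher's exact test, p = 2.8e-20, adjusted p = 2.2e-19 over 8 overlaps). Of the 189 reverse regions 9 were lower in the cKO, where 1.27 would be shared, and 0 were higher (odds ratio 7.61, interval 2.97 to 13.6, Fisher's exact test, p = 5.9e-06, adjusted p = 1.6e-05). The overlap was partial, since 10.2% of the tested regions called higher in the cKO held the combined call. The Fisher p-values of these overlaps count neighbouring regions as independent and are therefore too small.

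Shared gains included the enhancers in Mad1l1 and Gm12824 and enhancers in Efna5, an ephrin gene (chromosome 17, 62997502 to 63010537), and Auts2 (chromosome 5, 132643949 to 132646493), with knockout log2 fold changes of 0.93, 0.78, 0.59 and 0.77 in the authors' deposited table. Others lay in Pepd, the prolidase gene, Fto, an RNA demethylase gene, and Rora, at 0.60, 0.45 and 0.56 in the authors' deposited table. Fat1, a cadherin gene, held 2 of them, at 0.42 and 0.41 in the authors' deposited table, and Slit1, an axon guidance gene, 1 at 0.45 in the same source, the authors' deposited table. Knockout FDRs of the Fat1 and Slit1 enhancers were 0.16, 0.18 and 0.16 in the authors' deposited table, so none of these passed 0.05. The gains named before them did. Shared losses included those in Slamf1, Camk1d, a calmodulin kinase gene, and Srgap3, a Slit-Robo GTPase-activating protein gene, at -0.41, -0.34 and -0.28 in the authors' deposited table. Their knockout FDRs were 0.061, 0.35 and 0.21 in the authors' deposited table, so none of these passed 0.05. The loss in Wdr66, at -0.59, had a knockout FDR of 0.049 in the authors' deposited table. The exception, higher in the knockout and lower in the cKO, was an enhancer in Otud3, at 0.31 with a knockout FDR of 0.14 in the authors' deposited table.

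**Figure D4:**
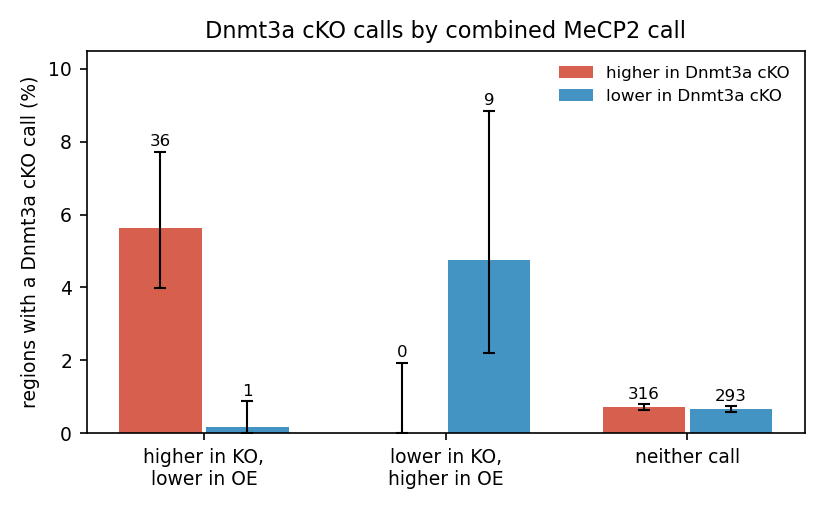
Percent of regions called higher (red) or lower (blue) in the Dnmt3a cKO (y axis) among regions by combined MeCP2 call (x axis). Exact 95% intervals for counting error, which take regions as independent, and the number of regions are drawn at each bar. Regions higher in the knockout stand at 5.64% for higher and 0.157% for lower in the cKO, regions lower in the knockout at 0 and 4.76%, and regions with neither call at 0.711% and 0.660%.

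Among the gene lists fixed before the data were examined, the very long neuronal genes held the only regions past the knockout FDR, both in Auts2. They were 2 of 732 regions over all regions tested and 1 adjusted over the list alone, at log2 fold changes of 0.77 and 1.04 in the authors' deposited table. Over all 63596 regions 207 passed. In this list 12 of 682 enhancer and ua_acetylpeak regions had the combined call with a knockout gain, where 638 of all 45252 labelled regions had it. Among them were enhancers of Nrxn1, Nrxn3 and Macrod2 at 0.39, 0.41 and 0.45, with knockout FDRs of 0.072, 0.19 and 0.34 in the authors' deposited table. The reverse call was held by 1 region, in Dlg2, at -0.54 in the authors' deposited table. The list as a whole did not stand apart from other regions (limma's pre-ranked camera, adjusted p = 0.71 in the knockout and 0.62 in overexpression), but with 1 value per gene it was lower in overexpression (adjusted p = 0.045). In overexpression camera did not call it among promoters alone (adjusted p = 0.51) or enhancer and ua_acetylpeak regions alone (0.93). Circular shifts did not call it there either (adjusted p = 0.59). The Auts2 locus also held regions called higher in the Dnmt3a cKO, 6 of its 46 enhancer and ua_acetylpeak regions.

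Ribosomal protein genes had higher H3K27ac in overexpression as a group (camera, adjusted p = 3.9e-06), with a median of 0.13 over 73 regions and 57 of them at or above 0. The list is taken by symbol and includes pseudogenes, and no member passed the FDR alone or adjusted over the list alone, with 4 higher and 2 lower at an unadjusted p below 0.05. Circular shifts of the statistics along the genome gave an adjusted p of 0.0026, the smallest they can give, and for the knockout, where the median was -0.044, one of 0.016. Camera did not call the knockout list over all regions (adjusted p = 0.10), with 1 value per gene (0.37), against promoters alone (0.76) or with methylation removed (0.42, in the higher direction). Against promoters alone the overexpression p was 0.034, and 0.68 once CA and CG methylation were removed (camera, adjusted).

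Inhibitory neuron marker genes had lower promoter H3K27ac in overexpression than other promoters (camera on 9 promoters, adjusted p = 0.0019, and 5.9e-06 with methylation removed). Adarb2, Pvalb, Gad2, Lhx6 and Reln promoters stood at -0.39, -0.31, -0.29, -0.29 and -0.25 in the authors' deposited table. Those of Dlx2, Dlx5 and Gad1 stood nearer 0, at -0.12, -0.10 and -0.07, and that of Slc32a1 at 0.03, in the authors' deposited table. Over all 22 regions of the inhibitory list the adjusted p was 0.17 with camera and 0.25 with circular shifts. Camera gave 0.93 in its enhancer and ua_acetylpeak regions and, with 1 value per gene, again in the lower direction, 0.022. At an unadjusted p below 0.05, 0 of these regions were higher and 0 lower in overexpression. Promoters of oligodendrocyte, astrocyte and microglia markers were lower as groups too (camera on promoters, adjusted p = 0.0026, 0.028 and 0.028), with an Mbp promoter, the gene of myelin basic protein, at -0.42 in the authors' deposited table. With methylation removed these 3 gave adjusted p-values of 0.15, 0.87 and 0.85, and over all regions 0.052, 0.71 and 0.32. With 1 value per gene the oligodendrocyte list was lower (adjusted p = 0.022), and the astrocyte and microglia lists were not called (0.21 and 0.14). In the knockout, promoters of excitatory neuron markers were higher than other promoters (camera, adjusted p = 0.028, and 0.17 with methylation removed), and with methylation removed those of microglia markers were lower (0.048, against 0.65 without). No region of the inhibitory, oligodendrocyte, astrocyte or microglia lists passed the FDR in either cohort, and 2 oligodendrocyte regions did in overexpression adjusted over the list alone.

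The other lists gave no call in either cohort over all regions, though adjusted over the list alone 2 excitatory neuron regions were lower in overexpression and 1 protocadherin region was higher and 1 lower in the knockout. Immediate early genes had 6 of 28 regions above 0 in the knockout and a median of -0.08 (camera, adjusted p = 0.10), with the Egr4 promoter at -0.23 in the authors' deposited table. Endothelial and pericyte markers had a knockout median of 0.11 (adjusted p = 0.19), and stress and glucocorticoid response genes one of 0.13 (0.19), with a Zbtb16 enhancer at 0.29 in the authors' deposited table. Oligodendrocyte precursor markers stood at a median of -0.11 over 8 regions (0.19), genes linked to MeCP2 in earlier work at 0.01 (0.67) and clustered protocadherins, of which 2 genes carried 8 regions, at -0.17 (0.32). Excitatory neuron markers had a median of 0.04 (0.32), with 2 Bcl11b enhancers holding the combined call at 0.25 and 0.33 in the authors' deposited table.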

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

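Apart from the FDR of 0.1, counts of regions at enhancers, Dnmt3a calls on autosomes, medians, quartiles, and regions above the median abundance for the correlation and the Dnmt3a calls, the alternatives here were chosen after seeing the data. The 24 alternatives for differences between classes or methylation deciles and the second test of the 28 named regions kept the sign of the main value. For the second test equal signs are weak support, since its knockout fold changes correlated at 0.981 with those of the first. No paired analysis was possible because the tables hold no values per library, and for the same reason other normalizations, filters, pseudocounts, a joint fit, another count tool, leaving out a mouse, an estimated list correlation and other splits of the mice were not run. The weight of single libraries was therefore not examined, and differences between mice enter only through the authors' own tests.

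The 207 knockout regions became 428 at an FDR of 0.1, 10 in the authors' second test and 6415 at an unadjusted p of 0.05. The 4 overexpression regions became 7, 1 and 4771. Limited to enhancers, the Dnmt3a calls were 547 in place of 877, by construction of the smaller set. Of 28 named regions 7 passed the second test. For the other differences in value the cause was not tested.

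The enhancer-promoter difference was 0.093 with medians, 0.062 in the second test and 0.090 above the median abundance in the knockout, and -0.156, -0.087 and -0.125 in overexpression. The difference between enhancers inside and outside genes was 0.084, 0.060 and 0.072 in the knockout, and -0.054 in the second test in overexpression. Between CA deciles the knockout difference was 0.122 in the second test, 0.163 above the median abundance, 0.149 with quartiles and 0.092 by CG. The overexpression difference was -0.178 with medians, -0.114 in the second test, -0.203 above the median abundance, -0.163 with quartiles, -0.146 by CG and -0.211 with 2-week CA methylation.

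The correlation of knockout and overexpression, -0.388, was -0.508 above the median abundance, -0.424 in the second test, -0.401 at enhancers, -0.355 with abundance, length and class removed and -0.308 with methylation removed. The knockout difference between Dnmt3a calls was 0.203 in the second test, 0.259 above the median abundance and 0.328 at enhancers. Of the 26 list tests, 1 passed over all regions, 4 with 1 value per gene, 0 in enhancer and ua_acetylpeak regions (limma's camera, 2 at an unadjusted p below 0.05), 6 in promoter regions, 2 in promoter regions with methylation removed and 2 by circular shifts.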

Other observations

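Regions called lower in the Dnmt3a cKO were longer and had more reads than regions without a call. Their median length was 4016 bp and their median mean abundance 3.78 log2 CPM, against 2292 bp and 2.94 for regions without a call. Their gain in CA methylation per region from 2 to 8 weeks had a median of 0.341 percentage points, against 1.03 at regions called higher. Their mean fold change differed from that of regions without a call by -0.122 log2 units in the knockout (95% interval -0.138 to -0.106) and by 0.068 in overexpression (0.044 to 0.092), where their mean of -0.0028 compares with -0.071 over all regions. The rise of overexpression fold changes with read abundance (Spearman's rho 0.280 over all regions) was not removed from this difference.

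At enhancers inside genes Spearman's rho with gene length was 0.067 in the knockout (95% interval 0.041 to 0.093) and -0.057 in overexpression. The mean knockout fold change of these enhancers was 0.035 in genes under 50 kb and 0.089 in genes over 200 kb. At promoters rho was 0.063 and -0.174. Promoters of genes over 200 kb averaged -0.044 in overexpression, and those of genes under 50 kb 0.063. Neighbouring enhancers, a median of 16.1 kb apart, correlated at 0.23 in their knockout and 0.24 in their overexpression fold changes, and enhancers 50 places apart at -0.0046 and 0.0059.

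In the weighing that follows, the tests of the trend with abundance, of a shared wild-type group and of methylation as the source of the inverse relation were chosen after their results were seen, and the others before. The inverse relation of knockout and overexpression fold changes was set against 4 explanations. A trend with read abundance, length or class is argued against as the whole source, since r was -0.355 ± 0.0049 (SD over genome bins) with it removed, and a shared wild-type group would give a positive r where -0.388 was seen. For a shift in the share of neurons, the knockout fold change was averaged with the sign-reversed overexpression one. Neuronal marker regions differed from glial and vascular ones by 0.0135 ± 0.025 log2 units (SD over genes), where CA deciles differed by 0.192. A shift as large as that decile gap is argued against, and smaller ones are not excluded. Median CA methylation was 1.77% and 2.84% at inhibitory and excitatory marker regions, against 3.30% to 3.68% in the glial and vascular lists. This difference was not removed and could hide a shift. DNA methylation may account for part of the inverse relation, and r stayed at -0.308 ± 0.0049 with the deposited methylation values removed. Their coverage is unknown, so whether methylation is the whole source is not decided. GC content and a response of enhancers to MeCP2 level stay open, as untested, and a shift in cell types stays open, as undecided.

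The overlap of Dnmt3a cKO gains with the regions higher in the knockout and lower in overexpression had an odds ratio of 8.38. Greater power at regions with more reads is argued against as its source, since the ratio was 7.35 (95% interval 4.85 to 10.0) within strata of abundance. Within strata of abundance and CA methylation it was 3.99 (2.63 to 5.40), so CA methylation in these tables may carry a part of the overlap. Whether CA methylation carries the whole is not decided, since its coverage is unknown and error in it would leave the strata incomplete. Methylation in the cKO itself was not analysed here, so what Dnmt3a loss does to it at these regions stays open, as untested.

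The regions higher in the knockout and lower in overexpression lay close together. Of the 638 regions, 265 had another within 100 kb, against a mean of 98.7 and a highest value of 140 in 1000 shuffles of the call within strata of CA methylation and abundance. Abundance and the deposited methylation level of single regions are thus argued against as the whole source. Error in the methylation values, whose coverage is unknown, was not allowed for. Domains that respond together, single genes such as Rora that hold many enhancers, and mapping or composition effects shared by neighbours stay open, as untested.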
